A study of Danio rerio with 8 samples.

How the data were processed

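Whole wildtype zebrafish (Danio rerio) embryos were sampled at 2 developmental stages, with and without low oxygen, and their total RNA was measured on microarrays. The gastrula samples were at the shield stage at 6 h of development, and the segmentation samples had 8 somites at 12 h. Per the labels' protocols, hypoxic embryos were kept in medium equilibrated with nitrogen to under 1% oxygen. Per the series' design text, exposure lasted 1 to 2 h and each sample pooled 12 to 15 embryos. RNA was extracted with TRIzol, and cDNA was labelled with Cy3 or Cy5, per the labels' protocols. The labels name 4 groups of 2 biological replicates, and each group holds 1 Cy3 and 1 Cy5 sample.

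The deposited value table holds log2 values summarised with RMA, per the submitters' processing notes, which give no version. RMA normally subtracts background, equalises the distributions of probes and summarises probes by median polish. The log2 scale was inferred from the values, which ran from 6.85 to 15.96 on arrays with values, and is not stated in the sources used here. The array design, the scanner and the software were not given in the sources used here. Whether samples of opposite dye shared an array is likewise unknown, so samples were counted, each as 1 array. The column of the second hypoxic segmentation sample held 0 values, and that sample was not analysed here. The fits therefore used 7 arrays, with 1 array for hypoxic segmentation embryos. Array medians were close, between 8.51 and 8.74. The interquartile range differed more, from 2.18 to 2.31 on the hypoxic gastrula arrays and from 2.75 to 2.86 on the normoxic gastrula arrays, so the deposited rows were not equalised across arrays. The number of arrays limits the precision, and signal over background was not used here. P-values measure the spread between these samples.

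The table has 37157 rows. Row identifiers were matched without versions to the RefSeq transcripts of a gene table of assembly GRCz12tu, used for names alone. Of 3055 rows with RefSeq transcript identifiers, 2663 matched 1 symbol each and 392 had no match. The remaining rows carry Ensembl-type (10153), Vega-type (11285), ZV (6756), TC (3779) or other (2129) identifiers and were tested without a name. The named rows cover 2650 symbols, of which 13 have more than 1 row, and a gene was represented by its row with the highest mean. Named genes are thus 7.17% of the rows, and a gene that is absent from the text may have an unnamed row.

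The model was chosen before the data were examined. It was a linear model with the 4 groups and the labelling dye as a covariate over all arrays, in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation. Tests were two-sided, with Benjamini-Hochberg adjustment over all rows and an adjusted p threshold of 0.05. It left 2 residual degrees of freedom, with 2.92 prior degrees of freedom. The contrasts were the hypoxia difference at each stage, their mean, the difference between them, and the difference between the stages in normoxia. Errors of differences are standard errors (SE) of this fit.

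Gene lists were fixed before the data were examined, 22 in all. Of these, 13 had at least 3 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. Members were also counted after adjustment over the list alone. That count was not adjusted over the lists, and in the shortest lists it is close to an unadjusted p. The list of genes that the study had singled out had 0 measured members. The rule for named genes took, for each stage's hypoxia difference, up to 8 genes in each direction past the threshold with both hypoxic arrays beyond both normoxic ones. Where fewer than 6 passed, it took the 10 with the smallest p, as values that did not pass. It added up to 4 members of each list with a member past the threshold, and 10 genes to be named if measured, of which bnip3 alone was. For the difference between the stages' responses it took up to 6 genes in each direction past the threshold, for the stage comparison the 5 largest changes in each direction and 6 stage markers, of which 0 were measured, and for the mean over stages the 5 smallest p in each direction. List members outside this rule, such as those past the threshold over the list alone, were named after their values were seen. The result of 1 list member is not reported here.

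Other settings were a fit without dye, replicate number within stage as a block, arrays of 1 stage or of normoxia alone, quantile normalization of the rows again, and median centring. Further ones left out the lowest 25% of rows by mean level, let the prior variance follow intensity or be robust, averaged rows of a gene, required an absolute log2 change of 1, used an adjusted p of 0.1, or left out each array in turn. Replicate number in place of dye, a crossed pairing at the gastrula stage, set tests after quantile normalization, and the fit without dye after quantile normalization were added after the data were seen.

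The fit was tested on simulated data with the real row means and residual spreads over 37157 rows. Each row's estimated residual SD was taken as its true spread, so recovery in the real data may differ. With 200 rows changed, 50 for each size, the fit with dye recovered 4% of 4-fold and 60% of 16-fold changes (log2 of 2 and 4) at the gastrula stage, and 0% of either at the segmentation stage. Without dye the shares were 46% and 90% at the gastrula stage and 28% and 78% at the segmentation stage. With 10% of rows changed, the fit with dye recovered 77.4% of 4-fold changes at the gastrula stage and 67.3% at the segmentation stage.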

Results

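Expression was measured on arrays in whole zebrafish embryos at the gastrula stage (shield, 6 h) and at the segmentation stage (8 somites, 12 h), after normoxia or after 1 to 2 h at less than 1% oxygen. Values were analysed for 2 normoxic and 2 hypoxic gastrula samples, 2 normoxic segmentation samples and 1 hypoxic segmentation sample. Values are log2, as inferred from their range, and differences are differences of group means adjusted for dye. Replicates correlated over rows with Pearson's r of 0.975 in normoxic gastrula, 0.973 in hypoxic gastrula and 0.978 in normoxic segmentation embryos. The hypoxic segmentation array correlated at 0.973 with normoxic segmentation replicate 1, as closely as replicates did, and at 0.953 with replicate 2. Between hypoxic and normoxic gastrula arrays r ran from 0.880 to 0.958. The hypoxic segmentation group has no replicate, so its array was assumed to vary like those of the other groups.

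The comparison of the stages in normoxia gave the size of normal developmental change and checked the stage labels. Between gastrula and segmentation, 4 of 8 measured somite and muscle genes rose, and 2 of 4 maternally supplied and early zygotic regulators fell. The homeobox gene meox1 (NM_001002450), expressed in somites, rose by 3.01 ± 0.38 (SE) on the log2 scale, from 11.04 to 14.05. The pluripotency factor nanog (NM_001098392) fell by 3.52 ± 0.35, from 14.3 to 10.7 (n = 2 arrays per group; limma adjusted p = 0.015 and 0.0082). In all, 3749 of 37157 rows passed, 2308 higher and 1441 lower at the segmentation stage, of which 101 and 85 had a gene symbol. Without any adjustment, 8761 rows had p under 0.05, where 1858 are expected by chance.

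The largest named rise was that of fstl1a (NM_001017860), a follistatin-like secreted protein, by 4.1 ± 0.30 (adjusted p = 0.0045). Next came zgc:162608 (3.50 ± 0.22), the tropomyosin gene tpm4a (3.43 ± 0.34), zgc:136410 (3.15 ± 0.19) and uraha, an enzyme of uric acid breakdown (3.13 ± 0.37). The lipoxygenase gene alox5b.3 (NM_001020578) fell by 3.96 ± 0.54 (adjusted p = 0.017), from 14.7 to 10.7. The others with large falls were nanog, zgc:153911 (-3.30 ± 0.42), fam113 (-2.97 ± 0.30) and the autophagy gene map1lc3c (-2.93 ± 0.27).

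Of 8 measured somite and muscle genes, 4 rose and 0 fell over all rows tested, and 5 rose when adjusted over the list alone. Beside meox1 these were ripply1, a corepressor that acts at somite boundaries (1.41 ± 0.19), smyd1b, a methyltransferase of muscle (1.40 ± 0.21), uncx4.1 (1.13 ± 0.22) and, over the list alone, the actin gene acta1b (0.95 ± 0.23). The list stood above other named genes by camera (adjusted p = 7.9e-05, but adjusted p = 0.55 with an estimated correlation). Of 4 maternal and early zygotic regulators, nanog and the egg coat gene zp2.2 (-1.28 ± 0.22) fell, and over the list alone the histone mRNA-binding gene slbp2 (-1.16 ± 0.33) also fell. The fourth member, sox19b, differed by -0.27 ± 0.22. Camera gave adjusted p = 0.0098 for this list, and adjusted p = 0.745 with an estimated correlation. The 3 measured of 49 listed ribosomal protein genes differed by 0.44 to 0.75 (camera adjusted p = 0.038, and adjusted p = 0.745 with an estimated correlation), and of these rpl6 passed over the list alone.

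Single members of other lists passed as well, out of 95 list members measured, 12 of which passed over all rows. The lipid carrier gene fabp1b.1 rose by 3.0 ± 0.19 and agr1, of mucous and epidermal cells, by 2.60 ± 0.35. The collagen-modifying enzyme gene plod2 rose by 1.22 ± 0.24 on its brighter row (0.43 ± 0.23, not passing, on the other) and the extracellular superoxide dismutase sod3a by 1.3 ± 0.18. The cyclin gene ccna2 fell by 1.86 ± 0.25, and osr1, a gene of early mesendoderm, fell by 1.26 ± 0.24. The number of calls rests on few arrays: it was 744 without segmentation normoxia replicate 1 and 619 without segmentation normoxia replicate 2. It was 6036 without gastrula normoxia replicate 1, and 1918 without either hypoxic gastrula replicate.

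**Figure D1:**
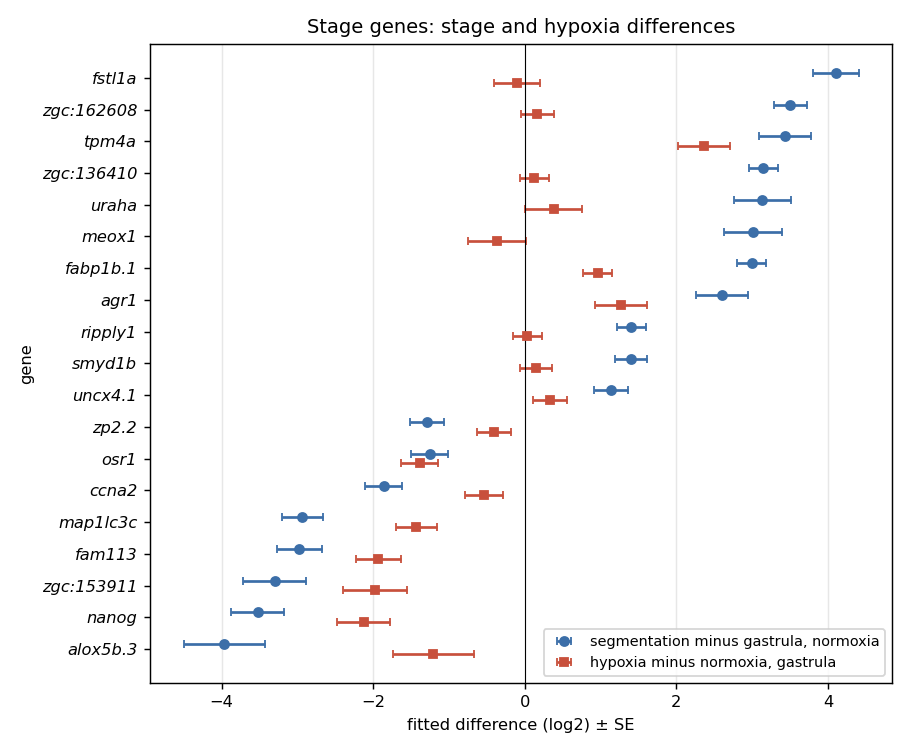
Fitted log2 differences of genes that passed between the stages in normoxia (blue circles, segmentation minus gastrula) and their hypoxia differences at the gastrula stage (red squares, hypoxia minus normoxia), with bars of 1 SE on the horizontal axis and genes on the vertical axis. The stage difference runs from 4.1 for fstl1a to -3.96 for alox5b.3, and under hypoxia nanog lies at -2.12 and tpm4a at 2.37.

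The hypoxia comparison at the gastrula stage asked how embryos in early development respond to loss of oxygen. Values of impact (NM_001005595), a regulator of the translation kinase GCN2, averaged 13.0 in normoxic and 10.8 in hypoxic gastrulae, a difference of -2.22 ± 0.21 on the log2 scale (4.67-fold). The difference was -2.52 ± 0.21 for trappc6b (NM_001006029), a vesicle-tethering subunit, and 1.63 ± 0.35 for bnip3 (NM_001012245), a HIF target that acts in mitophagy. None of these passed after adjustment over all rows in the fit with dye (n = 2 per group; limma adjusted p = 0.058, 0.058 and 0.081). In that fit 0 rows passed, although 9945 rows had an unadjusted p under 0.05, 4070 higher and 5875 lower, against 1858 expected by chance. Shifts of whole arrays move many rows together, so a count over 1858 does not by itself show an effect of hypoxia. In an additive limma fit, a split that tests gastrula normoxia replicate 2 alone against the rest gave 10743 rows.

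The same fit had 4287 rows with an adjusted p under 0.1, 1482 higher and 2805 lower. The fit without the dye term had 3025 rows under 0.05, 1005 higher and 2020 lower. The dye term itself had 0 rows past the threshold and 681 at an unadjusted p under 0.05, and the median residual SD was 0.224 with it and 0.225 without it. The dyes are balanced at this stage, so the fitted differences were the same in both fits and only their errors and degrees of freedom changed. With dye fitted, 1300 rows passed after median centring, 2002 without the lowest 25% of rows and 1712 with an intensity trend, so the call for single genes depends on these settings as well as on dye.

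The 10 named genes with the smallest p were all lower under hypoxia, with adjusted p = 0.058 each. In normoxic gastrulae their means, from 10.2 for rab8a to 13.0 for impact, lay above the array medians. Bright rows were lower as a whole in the deposited values. With rows in 10 equal bins by mean level, the median difference was -0.50 in bin 8 and -0.56 in bin 9. Besides impact and trappc6b these were slc25a11, a mitochondrial oxoglutarate carrier (-2.47 ± 0.27), cdkal1, a tRNA-modifying enzyme (-2.32 ± 0.26), and the RNA-binding gene rbm4.3 (-2.04 ± 0.21). Also in this set were pym1, which acts on exon junction complexes (-1.96 ± 0.19), the transcription factor gene ets2 (-1.90 ± 0.20), the small GTPase gene rab8a (-1.79 ± 0.20), pudp (-1.71 ± 0.20) and timm10b, of mitochondrial protein import (-1.66 ± 0.17). Without the dye term all 10 passed, with adjusted p from 0.019 for impact to 0.031 for timm10b. Each kept its direction in every setting that was run. Many of these settings leave the fitted gastrula difference unchanged, and the genes were picked for small p, so direction had little room to change.

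Among the fixed lists, 6 of 51 listed HIF pathway genes were measured, so most of the list is absent. All 6 lay above 0 (median 0.58), led by bnip3, its relative bnip3la (0.93 ± 0.36) and vhl, which targets HIF for degradation (0.88 ± 0.26). Over all rows 0 of the 6 passed, and adjusted over the list alone bnip3 rose (adjusted p = 0.035). The list's camera adjusted p was 0.058, and adjusted p = 0.62 with an estimated correlation. After quantile normalization again the camera adjusted p was 0.028, with 5 of 6 above 0 and a median of 0.91. The 7 measured genes of oxidative stress and iron also lay above 0 (median 0.36, camera adjusted p = 0.058, and 0.094 after quantile normalization again), of which hamp, encoding the iron hormone hepcidin, rose over the list alone (0.98 ± 0.19). The 9 blood and endothelium genes lay above 0 with a median of 0.18 (camera adjusted p = 0.079, and 0.23 after quantile normalization again), and runx1, a regulator of blood stem cells, rose over the list alone (1.23 ± 0.19). Centring each array on its median moved the median difference of all rows by -0.18 and the share of higher rows at an unadjusted p under 0.05 from 40.9% to 25.2%, and then 5, 5 and 4 members of these 3 lists lay above 0. After quantile normalization again 5, 5 and 8 did.

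The 4 maternal and early zygotic regulators lay below 0 (median -0.72, camera adjusted p = 0.058, and after quantile normalization again 0.18, with 3 of 4 below 0), and nanog fell when adjusted over the list alone (-2.12 ± 0.35, adjusted p = 0.0074). Of 7 heat shock proteins and chaperones, 3 fell over the list alone. They were stip1, a Hsp70-Hsp90 adaptor (-1.41 ± 0.27), the Hsp110 family gene hspa4a (-1.94 ± 0.56) and the chaperonin gene cct2 (-1.30 ± 0.38). The camera adjusted p of that list was 0.32. Other members that fell over their list alone were the replication helicase gene mcm5 (-1.48 ± 0.26), osr1 (-1.39 ± 0.24), the endoplasmic reticulum chaperone gene calr (-1.34 ± 0.30) and the ATP synthase gene atp5f1b (-1.17 ± 0.21). Those that rose over their list alone included the myogenic and neural crest gene pax7a (2.19 ± 0.36), agr1 (1.27 ± 0.35) and fabp1b.1 (0.96 ± 0.19). In all, 7 list members rose and 8 fell by that measure, and 0 of 95 passed over all rows.

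The lists for oxidative phosphorylation (6 measured, camera adjusted p = 0.83), unfolded protein response (4, 0.52), cell cycle (3, 0.52), sterol synthesis (14, 0.99), somite and muscle (8, 0.52), insulin and gluconeogenesis (6, 0.75), glycolysis (3, 0.75) and ribosomal proteins (3, 0.67) had no call. The median, mean and test differed in sign for oxidative phosphorylation (0.04, 0.04, test lower), insulin and gluconeogenesis (0.09, -0.10, test higher) and sterol synthesis (-0.10, 0.01, test lower), and in the other comparisons such lists had no call either. Glycolysis was represented by 3 of 39 listed genes, pdk3b, pfkmb and pdk2b, which differed by 0.14, -0.04 and 0.10. The remaining lists had 2 measured members or fewer. Of these, the apoptosis genes pmaip1 and casp3b differed by -0.95 ± 0.46 and 0.29 ± 0.20, the immediate early genes egr3 and per1b by 0.20 ± 0.23 and -0.17 ± 0.20, and the neural genes her3 and fezf2 by 0.97 ± 0.38 and 0.34 ± 0.20. The neural crest genes tfap2c and prdm1a differed by -0.32 ± 0.20 and 0.79 ± 0.28, and the notochord genes cav1 and lamb1a by 1.05 ± 0.36 (-0.06 ± 0.20 on the dimmer row of cav1) and -0.26 ± 0.18. The second members of the lists that hold osr1, agr1 and fabp1b.1 were hhex (1.05 ± 0.53), krt97 (-0.16 ± 0.26) and hnf4b (-0.59 ± 0.37). Apart from osr1, agr1 and fabp1b.1, no member of these lists passed over the list alone. Values moved with level as well: with rows in 10 equal bins by mean level, the median difference was 0.20 in bin 5 and -0.56 in bin 9, and after quantile normalization again it was 0.0065 and -0.07. Leaving out gastrula normoxia replicate 1 gave 8275 rows past the threshold, and leaving out any other array gave 0.

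**Figure D2:**
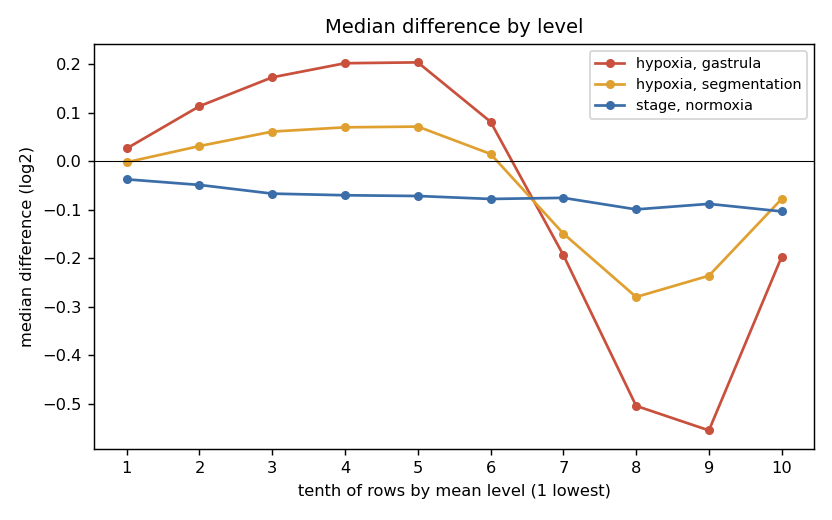
Median log2 difference of rows in 10 equal bins of mean level (horizontal axis, bin 1 lowest) for hypoxia at the gastrula stage (red), hypoxia at the segmentation stage (orange) and the stage comparison in normoxia (blue). The hypoxia medians are 0.20 and 0.07 in bin 5 and -0.56 and -0.24 in bin 9, while the stage medians stay between -0.04 and -0.10; after quantile normalization again, which is not plotted, the hypoxia medians are 0.0065 and -0.02 in bin 5 and -0.07 and -0.0032 in bin 9.

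The same comparison at the segmentation stage rested on 1 hypoxic array against 2 normoxic arrays. The value of hsp70.3 (NM_131397), an inducible heat shock protein gene, was 11.8 in the hypoxic sample and averaged 8.75 in its controls, a difference of 3.03 ± 0.23 on the log2 scale (8.19-fold). The difference was 1.90 ± 0.28 for chordc1a, an Hsp90 cochaperone gene, and 2.68 ± 0.43 for ptk7a, a receptor of planar polarity signalling. In the limma fit with dye 0 rows passed (smallest adjusted p = 0.29, that of hsp70.3), with 2634 rows at an unadjusted p under 0.05, 916 higher and 1718 lower, a higher share of 34.8% that was 46.9% after quantile normalization again. The fit without dye had 9 rows, 5 higher and 4 lower, of which hsp70.3 was the 1 with a symbol (adjusted p = 0.039).

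The other genes among the 10 with the smallest p were impact (-1.60 ± 0.27), rac1b, a Rac GTPase gene (-1.31 ± 0.24), b3gnt3.1, a glycosyltransferase gene (-1.25 ± 0.23), cdkal1 (-1.78 ± 0.34) and ets2 (-1.36 ± 0.26) on the lower side. On the higher side were the homeobox gene meis2b (1.41 ± 0.27) and tfb1m, a mitochondrial rRNA methyltransferase gene (1.43 ± 0.28). Their adjusted p ran from 0.60 to 0.61 with dye. The HIF target bnip3 differed by 0.65 ± 0.46 (adjusted p = 0.89).

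Adjusted over the list alone, 4 list members rose and 0 fell. They were hsp70.3 (adjusted p = 0.00032) and, among somite and muscle genes, pax7a (1.68 ± 0.47), the repressor gene prdm1a (1.28 ± 0.36) and ripply1 (0.99 ± 0.24). Of the 6 HIF pathway genes 4 lay above 0, with a median of 0.42 and a camera adjusted p of 0.53, and of the 7 heat shock genes 3 lay above 0 (median -0.17, mean 0.36, camera adjusted p = 0.57). For this comparison 0 of the 13 lists had a call, and the camera adjusted p of somite and muscle was 0.44 (median 0.02, and adjusted p = 0.71 with an estimated correlation). After quantile normalization again it was 0.035 (median 0.20), and after median centring the median was -0.04. In the simulation with 200 changed rows the fit with dye recovered 0% of 16-fold changes at this stage. Changes of that size in few rows were thus not detectable in that setting, and detection in the data may differ.

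**Figure D3:**
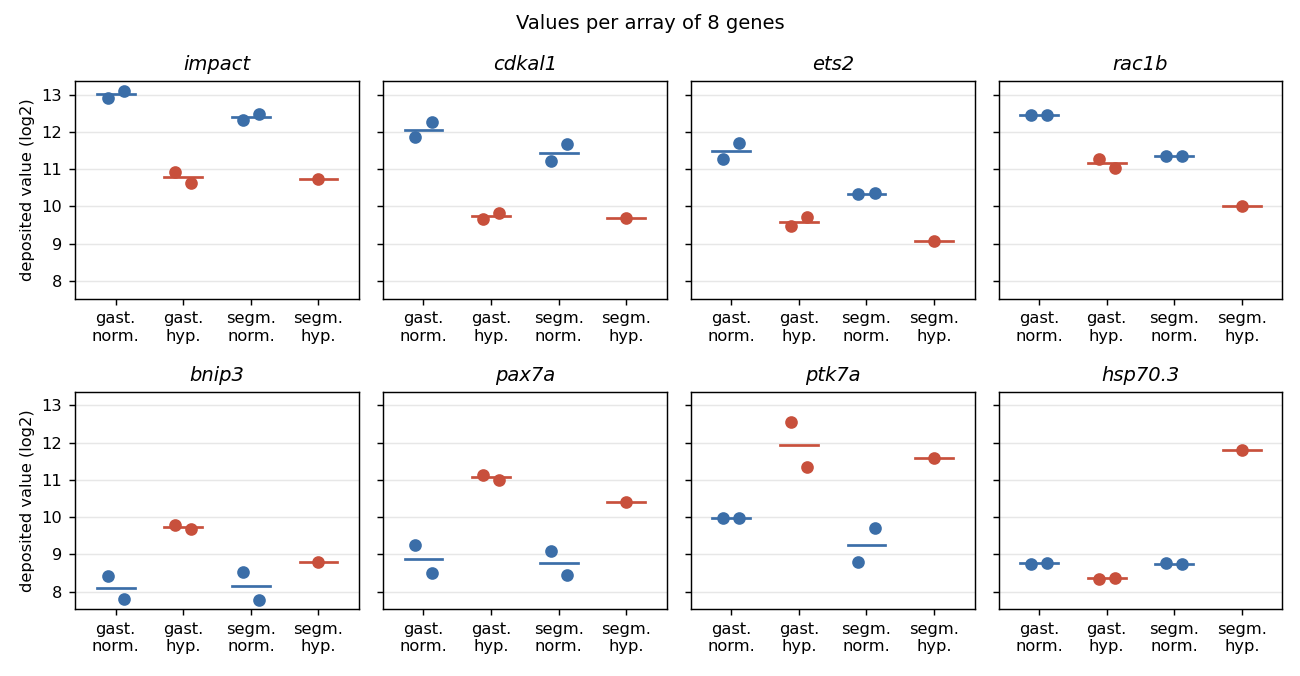
Deposited log2 values (vertical axis) of 8 genes on each array in normoxic (blue) and hypoxic (red) gastrula and segmentation embryos, with a point per array and a line at the group mean. The impact values average 13.0 and 10.8 in normoxic and hypoxic gastrulae, and hsp70.3 stands at 11.8 on the hypoxic segmentation array against 8.75 in its controls.

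Averaged over both stages, the hypoxia difference was negative for impact (-1.91), cdkal1 (-2.05), ets2 (-1.63), pym1 (-1.56) and timm10b (-1.38), and positive for ptk7a (2.33), numb, a Notch inhibitor gene (1.49), hsp70.3 (1.32), the Hedgehog effector gene gli2b (1.21) and gc, the vitamin D-binding protein gene (1.09). These are the 5 named genes with the smallest p in each direction, and none passed with dye (adjusted p from 0.076 to 0.080). Without dye all 10 passed, with adjusted p from 0.015 for impact to 0.038 for gc. With dye 0 rows passed in limma, 9139 had an unadjusted p under 0.05 and 2730 an adjusted p under 0.1. Without dye 3333 passed, 1118 higher and 2215 lower. Median centring moved the median of all rows by -0.12 and the higher share at an unadjusted p under 0.05 from 39.2% to 25.7%, and leaving out gastrula normoxia replicate 1 gave 7977 rows.

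Over the lists alone, 7 members rose and 8 fell on this average. Beside bnip3 (1.14 ± 0.29), vhl rose (0.76 ± 0.21), and the sterol enzyme gene mvda (-0.85 ± 0.14) and nanog (-1.77 ± 0.29) fell. For the list tests of the average, 0 of 13 had a call, and the smallest camera adjusted p was 0.20, for HIF pathway genes and for blood and endothelium.

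The hypoxia differences of both stages ran in parallel. Over 37157 rows they correlated with Pearson's r = 0.678 and Spearman's rho = 0.661, and 74.3% of rows had the same sign; r was 0.514 without gastrula normoxia replicate 1. The dye estimate, which draws on the gastrula arrays too, enters the segmentation difference alone. Without dye, where the comparisons have no sample in common, r was 0.719. Whether their samples shared arrays is unknown. Deviations of same-numbered normoxic samples of both stages correlated at 0.540, so shared error may be part of r. These are correlations across rows, which are not independent replicates. At an unadjusted p under 0.05, 587 rows were higher at both stages, where independent lists would share 100.3, and 1053 were lower at both, against 271.6. Without dye these were 960 against 178.9 and 1682 against 457.1. Both comparisons use the same residual variance of each row, so independent lists are not the value for no shared change. The single Cy3 and Cy5 pairs of gastrula arrays gave r = 0.724 with each other, and r = 0.618 and 0.526 with the Cy5 pair of segmentation arrays. The spread of the differences over rows was larger at the gastrula stage (SD 0.726) than at the segmentation stage (SD 0.494).

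**Figure D4:**
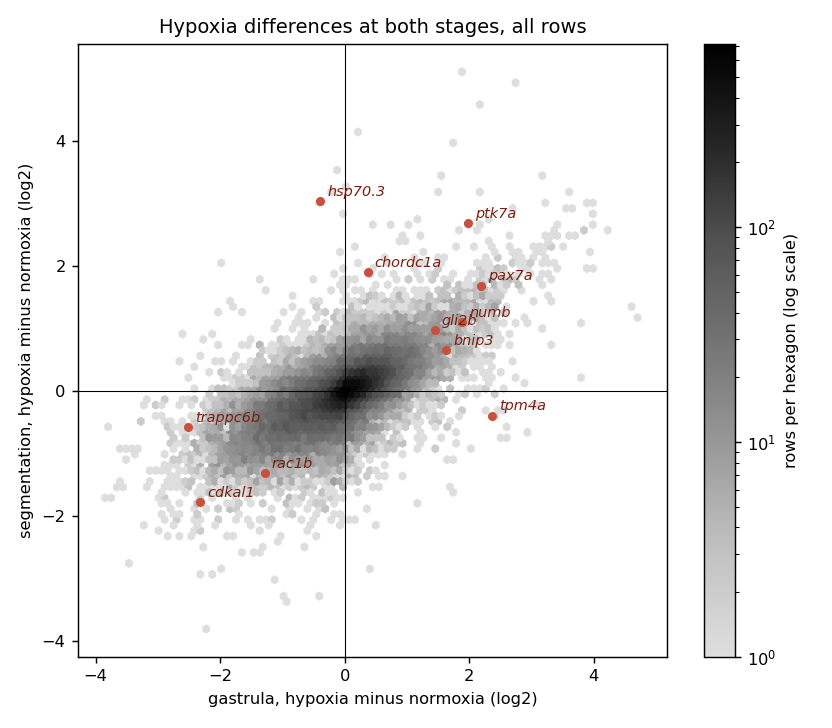
Hypoxia minus normoxia log2 differences of all 37157 rows at the gastrula stage (horizontal axis) and the segmentation stage (vertical axis), as counts per hexagon on a log grey scale, with 11 named genes in red. The cloud runs along the diagonal (r = 0.678), cdkal1 lies at -2.32 and -1.78, and hsp70.3 lies at -0.40 and 3.03.

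The test of a difference between the stages' hypoxia responses called 0 rows in limma with dye (smallest adjusted p = 0.875, 1569 rows at an unadjusted p under 0.05) and 0 without dye (1933 rows). Median centring moved the median of all rows by 0.12 and the higher share from 60.5% to 75.2%. Of the lists, heat shock proteins and chaperones differed, with a more positive response at the segmentation stage (median difference 0.50 over 7 genes, camera adjusted p = 0.023, and adjusted p = 0.55 with an estimated correlation). Over the list alone hsp70.3 differed, by 3.43 ± 0.29, since it lay at -0.40 ± 0.17 in hypoxic gastrulae. The lipid carrier gene fabp1b.1 also differed over its list alone, by -1.24 ± 0.31. In the gastrula hsp70.3 was lower by -0.39 and -0.40 in the single Cy3 and Cy5 pairs.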

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

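Tests of the heat shock pattern below were chosen after its list result was seen. The list of heat shock proteins and chaperones was the 1 list whose hypoxia response differed between the stages by a test of the difference itself (camera adjusted p = 0.023, but adjusted p = 0.55 with an estimated correlation). Without hsp70.3 the adjusted p of the list was 0.28, so the call rests on that gene, whose response differed by 3.43 on the log2 scale; the next largest differences, of hspa4a (1.76 ± 0.92) and stip1 (1.2 ± 0.43), did not pass over all rows or over the list alone. Quantile normalization of the arrays again left these differences at 3.68, 1.95 and 0.88 and took the median of the 7 members from 0.50 to 0.18, with members on both sides of 0 and a camera adjusted p of 0.047 for the list, which leaves open how far value distributions contribute to the rest of the list. The segmentation value comes from 1 hypoxic array, so an effect of that sample and a stage-specific heat shock response cannot be told apart. A hypothesis for an independent sample is that hypoxia may induce hsp70.3 and the Hsp90 cochaperone gene chordc1a at the segmentation stage.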

How the results depend on the processing

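Settings added after the data were seen are replicate number in place of dye, the crossed pairing, set tests after quantile normalization, and the fit without dye after quantile normalization. The number of rows past the threshold at the gastrula stage was 0 in the main setting. It was 3025 with no dye term, 1300 with median centring (219 higher, 1081 lower), 2002 with the lowest 25% of rows left out, 1712 with an intensity trend, 4287 at an adjusted p under 0.1, 1375 with replicate number in place of dye, 5348 with the crossed pairing, and 2272 with no dye term and quantile normalization again. For the average over stages, in place of 0, the same settings gave 3333, 0, 678, 433, 2730, 0, 2229 and 2138. At the segmentation stage the count was 9 with no dye term, 3 with no dye term and quantile normalization again, and 0 in every other setting run. The difference between the stages' responses had 0 calls in every setting. The stage comparison, 3749 in the main setting, fell to 1918 with normoxic arrays alone (1890 of them also in the main setting), was 5847 at an adjusted p under 0.1, and lay between 3543 and 5068 in the other settings that kept all arrays. With single arrays left out, counts ranged from 0 to 8275 at the gastrula stage and from 0 to 7977 for the average, both highest without gastrula normoxia replicate 1, and from 619 to 6036 between the stages. The correlation of both hypoxia responses, 0.678, ranged with single arrays left out from 0.514 (without gastrula normoxia replicate 1) to 0.701, and was 0.719 with no dye term. The cause of these differences was not tested. Fits with fewer terms keep more residual degrees of freedom, 3 without dye against 2 with it.

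With replicate number as a block, 0 rows passed for hypoxia at either stage or averaged, and the response correlation was 0.60. Same-numbered gastrula arrays deviated with a correlation of -0.146, and same-numbered normoxic arrays of both stages with one of 0.540. Replicate number and dye coincide at the gastrula stage, so the value of -0.146 cannot settle whether the numbers pair these samples. The crossed pairing, added after the data were seen, called 5348 rows at the gastrula stage and 2229 on average. The stage comparison has no value with this block, since each block lies within 1 stage, and was 4367 with replicate number in place of dye. With dye the 3 segmentation arrays alone leave no residual degrees of freedom and were not fitted, and without the hypoxic segmentation array its response has no value. Of the list results, 4 in the main setting, 0 held with an estimated correlation, fry called 2, both for the 3 glycolysis genes, quantile normalization again called 6, and the block gave 6 for hypoxia contrasts, where the main setting had 1, which was among these 6. For 42 named gene results, 589 of 748 alternative values kept their side of the threshold, 142 newly passed, 11 no longer passed, 6 values of single Cy3 or Cy5 pairs (of impact, rbm4.3 and rab8a) moved by over 1 SE, and 0 changed direction. Many settings leave a fitted difference unchanged, and most of these genes were picked for small p or large change, so a kept direction says little.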

Other observations

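The tests below with matched lists, different normoxic arrays and other splits of the arrays were set out before their results were seen; the limit of these splits to the number of arrays per stage, the correlation within bins of mean level, the test of mixed RNA and the genes of this paragraph were chosen after. The largest positive difference of a named gene in hypoxic gastrulae was that of ngfb, a nerve growth factor gene, at 3.98 ± 0.77 on the log2 scale, and it lay at 1.98 ± 1.00 at the segmentation stage (limma adjusted p = 0.075 and 0.79, and 0.036 at the gastrula stage without dye). The tubulin-modifying enzyme gene ttll11 lay at 2.52 and 1.76 at the 2 stages, and the muscle gene mybpc2b at 1.25 and 2.18. On the lower side psmd2, a proteasome subunit gene, lay at -1.86 and -1.39, and gkap1 at -2.43 and -0.97. None of these passed with dye. Between the stages in normoxia, 10 of 13 genes of mitochondrial ribosomal proteins (symbols that begin with mrp) lay above 0 with a median of 0.65, and mrpl17, mrps14 and mrpl14 rose, as did cyp2aa1, cyp2aa2, cyp2aa3 and cyp2aa9 among 24 cyp genes. Both families stood above other named genes by camera (adjusted p = 0.00043 and 0.00084 over 12 symbol families, but adjusted p = 0.58 and 0.68 with an estimated correlation).

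Hypoxic and normoxic arrays differed in more rows than any other grouping of the 7 arrays into 3 and 4 that was fitted. In an additive limma fit of stage, dye and treatment, 10971 rows had an unadjusted p under 0.05, and 90 passed after adjustment. Of the 33 splits into 3 and 4 arrays that could be fitted, 1, the real one, gave as many. The highest other count, 10743, came from splits that, with stage and dye fitted, test gastrula normoxia replicate 2 alone against the rest. Some other splits also repeat a test, so the 33 are not distinct tests. Treatment varies within stages, and the 17 splits that keep the number of arrays per stage are too few for a share under 0.05. Their highest other count was 10579, for both normoxic gastrula arrays with segmentation normoxia replicate 2. With stage fitted, that split still sets both normoxic against both hypoxic gastrula arrays and regroups the segmentation arrays alone. It thus carries the gastrula hypoxia difference and is not a grouping unrelated to treatment. The responses of both stages still correlated after quantile normalization again, with a median r of 0.599 within 10 bins of mean level, which argues against different value distributions of the arrays as the whole source of their likeness. No date or batch was used here, so a difference in handling between hypoxic and normoxic samples stays open beside an effect of low oxygen.

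In hypoxic gastrulae, rows that fall by the segmentation stage were already low. Different normoxic gastrula arrays were used in each comparison. Rows that fell by over 1 on the log2 scale between the stages had median hypoxia differences of -0.71 (3350 rows) and -0.82 (2331 rows). These lay below the lowest of 1000 random lists matched on mean level (-0.29 and -0.38). Rows that rose had medians of -0.04 and -0.08, above the highest (-0.17 and -0.16). The level was the mean over all arrays. In gastrulae, rows that fell were thus mostly brighter than their matches, and rows that rose were dimmer. Bright rows were lower on the hypoxic arrays, so the matched lists cannot tell that source from an effect on the embryos. The correlation of both comparisons was 0.271 with shared controls, and the covariance was 0.168. Simulated values with neither a hypoxia nor a stage difference gave 0.498 and 0.057. Real stage differences add spread that the simulation lacks, so 0.271 and 0.498 cannot be compared directly. With different normoxic arrays the correlations were 0.103 and 0.257. Both lay over the bound of 0.1 set for shared controls, the lower by a narrow margin, so part of the correlation may still come from those controls. After quantile normalization again the medians of rows that fell were -0.50 and -0.54, and the correlations were 0.084 and 0.239, on both sides of that bound, so value distributions and an effect on the embryos cannot be told apart for the correlation. Of rows that rose by over 3, 64.1% and 58.5% were higher in hypoxia. RNA from segmentation embryos would raise nearly all of them if its share were large. The size of such a share was not modelled, so a small one cannot be excluded.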
